A study of Mus musculus with 15 samples.

How the data were processed

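The series holds RNA sequencing of 15 mouse hearts after transverse aortic constriction, 5 libraries from each of 3 groups given saline, donepezil or encenicline. Per the submitters' processing notes, HISAT, featureCounts 1.5.0-p3 and DESeq 1.8.3 were used with the genome build GRCm38; the notes give neither the role nor the order of these tools. The deposited table gives FPKM for 54532 genes in the 15 libraries, with gene identifiers, symbols, lengths, biotypes and coordinates. The deposited FPKM values, times gene length and 1 constant per library, are whole numbers of reads to within 0.05 reads in 99.9 to 100% of values. The library size implied by these values was 0.925 to 1.15 times the recovered read total of a library. The step that made this factor is not stated in the notes. The gene symbols of the table included 27 that a spreadsheet had turned into dates, and all 27 were recovered from the gene identifiers.

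Libraries were grouped by title. For 2 of them, donepezil 1 and encenicline 1, the treatment field of the label names another group, and the counts of genes, the list calls, the named genes and the correlation of the drug effects were also computed without these and with the groups of the field. The labels do not say in so many words that each library is a single mouse, and that was taken from the numbering 1 to 5 in each group. No batch or date is given. No library was left out of the fit, and 0 sample columns stayed unmapped.

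Genes with at least 0.5 FPKM in at least 5 of the 15 libraries were tested, 13396 in all, of which 11648 are protein coding. A linear model on log2(FPKM + 0.5) with a mean-dependent prior for the variance (limma 3.58.1 in R 4.3.3, with the package data.table, version 1.17.8) was fitted to the 15 libraries at once without a block, and the 3 contrasts between groups were taken from it. The test is limma's moderated test, two-sided, with p-values adjusted by Benjamini-Hochberg over the genes tested in each contrast and called at an adjusted p under 0.05. Of 44 gene lists fixed beforehand, 26 of processes and 18 of cell types, the 34 with at least 5 tested members were compared with the other genes by limma camera with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists of each contrast. The calls were repeated with an estimated correlation and with limma fry. Members of a list were counted over all genes and adjusted over the list alone. The list score of a library is the mean over members of log2(FPKM + 0.5) after centring each gene on the 15 libraries, compared 5 against 5 by an exact two-sided permutation test. The pipeline was tested on simulated libraries with known changes. Each gene was drawn independently, so effects that the genes of a real library share were absent. Of 1.5-fold changes the pipeline recovered 69.0% in encenicline against saline, 60.0% in donepezil against saline and 71.5% in encenicline against donepezil. Of 2-fold changes it recovered 89.0%, 85.0% and 88.5%. False calls made up 4.24%, 4.61% and 5.60% of the calls.

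The genes named in the text follow a rule. For each comparison they are the protein-coding genes with a mean of at least 1 FPKM that passed, the 12 largest log2 fold changes upward and the 12 downward, filled to 5 by smallest p where fewer than 5 passed. To these come 15 genes named in advance (Ccrl2, Ccr2, Chrna7, Chrm2, Ache, Bche, Nppa, Nppb, Myh6, Myh7, Col1a1, Postn, Il1b, Cd68 and Adgre1) and, of each list described, up to 4 members by smallest p. Further members of the lists and some further genes are named as chosen after their values were seen: Fkbp5, Cebpd, Per1, Cpt1a, Cat and Gbp2 of donepezil against saline and those of the closing part on other biology. A few genes that the rule chose are not reported here. The lists described were picked from those fixed after their results were seen. The groups, tests, lists, the rule and the alternatives were fixed before the data were examined, apart from 2 alternatives added later.

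The alternatives were pseudocounts of 0.1 and 1, no filter and a filter at 2 FPKM, scaling by median ratios, by quantiles, to a sum without mitochondrially encoded genes and to the equal sum of TPM, only the 10 libraries compared, library weights with robust variances, a replicate block, limma voom on the recovered reads, the label alternatives above, and each library left out in turn. Scaling changed the split of calls: of donepezil against saline, 158 higher and 126 lower became 97 and 117 without mitochondrially encoded genes and 53 and 105 with TPM. Of encenicline against donepezil, 59 and 66 became 34 and 61, and 18 and 38. With TPM the median log2 fold change of all genes was -0.15, -0.08 and -0.07 in encenicline against saline, donepezil against saline and encenicline against donepezil.

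Reads recovered per library ran from 14496147 to 17176086, of which 17.4 to 27.0% were mitochondrially encoded. The median standard error of a log2 fold change was 0.11. For the shared saline libraries, unchanged groups were simulated against them and the saline libraries were also split between the drugs. Counts of genes were compared with 100 of the 126 splits of each pair of groups into 5 and 5. Intervals are 95% confidence intervals of limma's fit.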

Results

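RNA was sequenced from hearts of C57BL/6 mice with pressure overload from transverse aortic constriction (TAC, a band that narrows the aorta). After 4 weeks of TAC the mice were randomised, 15 per group, to physiological saline, to donepezil at 5 mg/kg/day or to encenicline at 2 mg/kg/day in the drinking water, and the hearts are labelled TAC 8 weeks. Donepezil inhibits acetylcholinesterase and so raises acetylcholine, and encenicline is an agonist of the nicotinic receptor encoded by Chrna7. The series asks which of these treatments does more for the failing heart, in a study of macrophages that carry CCRL2. The table holds 5 libraries per group, 15 in all, with no unoperated heart. The reads assigned to genes, recovered from the FPKM values and gene lengths, came to 14496147 to 17176086 per library (in units of 1e+06 reads, 15.9 ± 0.754 with saline, 15.6 ± 0.441 with donepezil and 15.8 ± 1.01 with encenicline, SD, n = 5 each). Of 54532 genes, 13396 reached 0.5 FPKM in at least 5 libraries and were tested, and 23005 were at 0 in every library. Over the genes tested, the correlation of log2 values across genes was 0.956 to 0.985 between libraries of one group. All fold changes below are on the log2 scale with their standard error (SE), positive where the first-named group is higher. The groups follow the library titles, which for donepezil 1 and encenicline 1 differ from the treatment field of the label (saline and donepezil).

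Donepezil against saline asked how raising acetylcholine changed the RNA of the pressure-overloaded heart. Of the genes that rose most, Pdk4, Ucp3 and Angptl4 limit glucose oxidation or serve the handling of fatty acids. Pdk4, a kinase that shuts pyruvate dehydrogenase, stood at 862 ± 194 FPKM with donepezil and 132 ± 40.4 with saline (SD, n = 5 each), a 6.63-fold difference (log2 2.73, SE 0.21, limma with Benjamini-Hochberg adjusted p = 5.55e-06), and its lowest donepezil library lay above its highest saline library. Ucp3, a mitochondrial carrier induced by fatty acids, stood at 52.5 ± 11.1 against 12.5 ± 1.81 FPKM (log2 2.00, SE 0.15, limma with Benjamini-Hochberg adjusted p = 5.55e-06), also with all 5 donepezil libraries above the 5 of saline. Angptl4, an inhibitor of lipoprotein lipase, stood at 15.2 ± 3.84 against 3.22 ± 1.17 FPKM (log2 2.10, SE 0.30, limma with Benjamini-Hochberg adjusted p = 0.00271). Mt2, a metal-binding protein induced by glucocorticoids, stood at 40.8 ± 9.45 against 8.56 ± 6.17 FPKM (log2 2.66, SE 0.57, limma with Benjamini-Hochberg adjusted p = 0.0254). Both had 5 of 5 donepezil libraries above the saline libraries. In saline 5, Mt2 was at 0.407 FPKM, below the pseudocount, so the size of its log2 fold change depends on that setting. The other saline libraries had 6.80 to 17.1 FPKM of Mt2. With single libraries left out, the log2 fold change of Mt2 ran from 1.96 to 3.03. On GRCm38, Pdk4 (ENSMUSG00000019577) lies on chromosome 6 at 5483351 to 5496309, Ucp3 (ENSMUSG00000032942) on chromosome 7 at 100472990 to 100486432, Angptl4 (ENSMUSG00000002289) on chromosome 17 at 33773750 to 33781575 and Mt2 (ENSMUSG00000031762) on chromosome 8 at 94172664 to 94173568.

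These genes belong to a list of 15 fasting and glucocorticoid response genes, all of which were higher with donepezil, with a median log2 fold change of 1.20. Of the 15, 10 rose and 0 fell in the test over all genes, and 15 rose adjusted over the list alone. Besides Pdk4, Ucp3, Angptl4 and Mt2 these 10 were Cdkn1a (1.68), Lcn2 (1.66), Fkbp5 (1.29), Cebpd (1.11), Fbxo32 (1.03) and Per1 (0.86), which act in cell cycle arrest, iron transport, glucocorticoid receptor folding, transcription, muscle protein breakdown and the daily clock. The list stood apart from the other genes (limma camera, Benjamini-Hochberg adjusted p = 1.32e-22 over 34 lists; adjusted p = 0.00134 with an estimated correlation). Its mean score per library separated the groups with no overlap (difference 1.40, exact two-sided permutation p = 0.00794, the smallest that 5 against 5 libraries allow; Benjamini-Hochberg adjusted p = 0.167 over the lists). Of the 6 lists called in this comparison by camera, it alone was also called with an estimated correlation, and limma fry, which does not compare a list with other genes, called it, the interferon list and the antioxidant list (Benjamini-Hochberg adjusted p = 1.65e-06, 0.0181 and 0.00866). The 6 became 12 without donepezil 4, 11 without donepezil 2 and 10 without saline 2 or without saline 3.

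The fatty acid oxidation list, which shares Pdk4, Ucp3 and Angptl4 with the fasting list, had 6 of 33 members that rose and 0 that fell, 10 and 0 adjusted over the list alone. Cpt1a (0.39), which encodes an enzyme of fatty acid entry into mitochondria, was another of the 6, a call that ended in 14 of 26 alternatives. The median of the list was 0.14, and its camera call was lost when the correlation was estimated (limma camera, Benjamini-Hochberg adjusted p = 1.64e-07; adjusted p = 0.937 with an estimated correlation). The median was 0.28 without donepezil 4, 0.076 without saline 3 and 0.090 without donepezil 2. Among the 16 antioxidant response genes 5 rose and 0 fell, both over all genes and adjusted over the list alone: Mt2, Hmox1 (1.27), Mt1 (1.13), Gclm (0.70) and Cat (0.32), with a list median of 0.26 (limma camera, Benjamini-Hochberg adjusted p = 7.50e-05; adjusted p = 0.115 with an estimated correlation). The Cat call ended in 15 of 26 alternatives. Mt1 stood at 428 ± 61.3 against 201.1 ± 63.4 FPKM (SD, n = 5 each).

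All 29 interferon response genes tested were lower with donepezil, with a median of -0.51. Of them 5 fell over all genes (Rtp4, -0.84; Gbp3, -0.84; Gbp7, -0.63; Gbp2, -0.54; Ddx58, which encodes the RNA sensor RIG-I, -0.36), and 22 fell adjusted over the list alone (limma camera, Benjamini-Hochberg adjusted p = 1.19e-17; adjusted p = 0.245 with an estimated correlation). Of 14 antigen presentation genes, 1 fell over all genes, the immunoproteasome subunit Psmb8 (-0.34), and 6 fell adjusted over the list alone, with a median of -0.30 (limma camera, Benjamini-Hochberg adjusted p = 0.00124; adjusted p = 0.937 with an estimated correlation). Of 22 cell cycle genes, 0 passed over all genes by limma and 1 fell adjusted over the list alone, with a median of -0.21 (limma camera, Benjamini-Hochberg adjusted p = 0.0264; adjusted p = 0.937 with an estimated correlation). That call ended without saline 3 (adjusted p = 0.145), saline 4 (0.185), donepezil 3 (0.053) or donepezil 5 (0.0535) in limma camera with Benjamini-Hochberg adjustment, with medians of -0.14, -0.11, -0.23 and -0.19. The Gbp2 call ended in 15 of 26 alternatives and the Psmb8 call in 16 of 26.

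Among the genes that fell most, Aplnr, the apelin receptor, fell from 18.4 ± 7.71 to 6.05 ± 2.68 FPKM (log2 -1.53, SE 0.29, limma with Benjamini-Hochberg adjusted p = 0.0146). Cited4, a transcriptional co-regulator that rises in the exercised heart, fell from 21.8 ± 5.22 to 7.69 ± 1.62 FPKM (log2 -1.44, SE 0.20, limma with Benjamini-Hochberg adjusted p = 0.0026). Fam78a, of unknown function, fell from 4.08 ± 0.838 to 1.44 ± 0.27 FPKM (log2 -1.23, SE 0.13, limma with Benjamini-Hochberg adjusted p = 0.000213), and Phyhip, a protein that binds a peroxisomal enzyme, from 7.03 ± 0.778 to 3.21 ± 0.309 FPKM (log2 -1.02, SE 0.09, limma with Benjamini-Hochberg adjusted p = 5.93e-05). Cited4 (ENSMUSG00000070803) lies on chromosome 4 at 120666572 to 120667820, Fam78a (ENSMUSG00000050592) on chromosome 2 at 32050055 to 32084857 and Phyhip (ENSMUSG00000003469) on chromosome 14 at 70457476 to 70468832. The other genes of the largest falls were Lrrc4b, Rtn4r, Mycn, Tfrc, Gal3st3, G0s2, Lrrc3b and Cbr2, from -1.33 to -1.04. The largest rises also included Slc10a6, Chac1, Cyp1b1, Rasd1 and Ddit4, from 1.82 to 1.43. In all, 284 genes passed, 158 higher and 126 lower, 275 of them protein coding, and 45 differed by at least 2-fold (32 higher, 13 lower). At an unadjusted p under 0.05 there were 2162 genes, 16.1% of those tested.

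None of the 14 tested genes named in advance for heart failure, macrophages and acetylcholine passed in this comparison. Ccrl2, the receptor of the series title, stood at 7.36 ± 2.58 FPKM with donepezil and 5.58 ± 1.1 with saline (log2 0.32, 95% confidence interval -0.08 to 0.73, limma with Benjamini-Hochberg adjusted p = 0.446). That change was 0.17 without donepezil 2 and 0.51 without donepezil 4. The log2 fold changes of the natriuretic peptide genes were 0.78 for Nppa and -0.56 for Nppb, and those of the myosin heavy chains 0.01 for Myh6 and 0.69 for Myh7. Without donepezil 4 they were 0.17 for Nppa and 0.068 for Myh7, and without donepezil 2 that of Nppb was 0.0765. They were 0.22 for Col1a1 and 0.13 for Postn (without donepezil 4, -0.53 and -0.82), -0.24 for Ache, -0.13 for Bche and -0.00 for Chrm2. Among the macrophage and monocyte genes they were -0.32 for Adgre1, -0.24 for Cd68, -0.06 for Ccr2 and -0.16 for Il1b, and without donepezil 4 they were -0.62, -0.48, -0.43 and -0.33. Without saline 3 the change of Il1b was 0.11, and without saline 3, donepezil 1, donepezil 2 or donepezil 5 that of Ccr2 was above 0. Chrna7 was not tested, since it reached at most 0.0716 FPKM, with 14 reads over the 15 libraries and 7 libraries at 0. The 14 cholinergic and vagal signalling genes had a median of -0.08 (limma camera, Benjamini-Hochberg adjusted p = 0.427).

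With donepezil 1 and encenicline 1 left out, 82 genes passed, 80 of them among the 284, and grouping by the treatment field gave 0. Leaving out single libraries gave 105 genes without donepezil 1, 132 without saline 2, 138 without saline 4, 144 without donepezil 3 and 148 without donepezil 2, and 409 without donepezil 4.

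**Figure D1:**
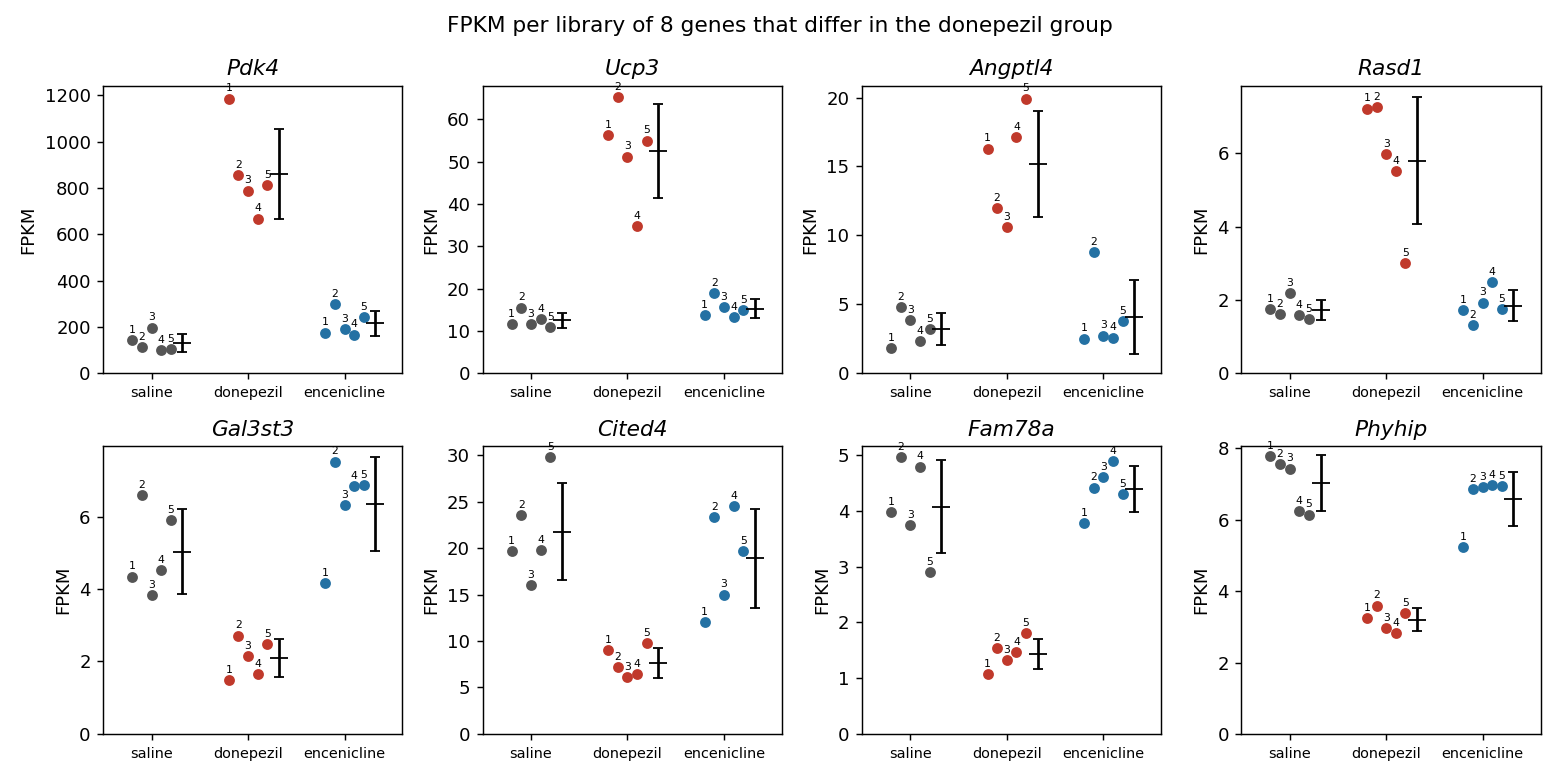
FPKM per library of 8 genes in the saline, donepezil and encenicline groups, with points labelled by replicate number and a bar at the mean ± SD (n = 5). The mean of Pdk4 is 132 with saline, 862 with donepezil and 216 with encenicline, and that of Fam78a is 4.08, 1.44 and 4.4.

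Encenicline against saline asked how an agonist of the Chrna7 receptor changed the same hearts. No gene passed with limma and Benjamini-Hochberg adjustment (0 genes, smallest adjusted p = 0.293), and voom on the recovered reads gave 0 as well. In limma 1235 genes, 9.22% of those tested, had an unadjusted p under 0.05, where chance gives 5% on average. Since genes vary together, that share can lie off 5% without any effect, and how far was not tested. Simulated changes of 1.5-fold in this comparison were recovered for 69.0% of 100 genes and changes of 2-fold for 89.0%. In that simulation genes were drawn independently and 165 were called, which loosens the adjusted cut-off. These shares may therefore overstate what the real comparison could detect. The genes below did not pass and are the ones with the smallest p. Calr3, which encodes a chaperone, stood at 9.77 ± 1.91 FPKM with encenicline and 5.7 ± 0.602 with saline (log2 0.71, SE 0.14, limma with Benjamini-Hochberg adjusted p = 0.368). The next on the higher side were Bcl6 (0.59), the iron exporter gene Slc40a1 (0.56), Tmem38b (0.50) and Dbr1 (0.34). On the lower side were the interferon response genes Ddx58 (-0.40), Ifit1 (-0.86) and Stat2 (-0.53) and the basement membrane genes Agrn (-0.49) and Nid2 (-0.53).

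Groups of genes differed in limma camera where single genes did not, with 19 of 34 lists called, 8 higher and 11 lower, and 0 of the 19 called with an estimated correlation or by limma fry (smallest Benjamini-Hochberg adjusted p = 0.0851, interferon response). Of 29 interferon response genes, 29 were lower with encenicline, with a median of -0.41 (limma camera, Benjamini-Hochberg adjusted p = 7.50e-23; adjusted p = 0.352 with an estimated correlation). Among them 0 fell in the limma test over all genes and 18 fell adjusted over the list alone, and Mx2 (-0.63) was among the 4 with the smallest p. The encenicline values of Mx2, 0.289 to 0.459 FPKM, lie below the pseudocount of 0.5, so its change depends on that setting. Of 22 cell cycle genes 20 were lower, with a median of -0.25, 0 past the limma test over all genes and 2 that fell adjusted over the list alone (limma camera, Benjamini-Hochberg adjusted p = 8.10e-08; adjusted p = 0.367 with an estimated correlation), with Mcm3 (-0.43), Kif20a (-0.51) and Mki67 (-0.45) at the smallest p. All 5 erythroid genes tested were lower, with a median of -1.004, and 5 fell adjusted over the list alone (limma camera, Benjamini-Hochberg adjusted p = 1.19e-04; adjusted p = 0.404 with an estimated correlation). They include Hba-a1 (-1.10) and Hbb-bs (-1.10), which are uncertain because counting could have split reads between them and their close paralogs. Of 22 NF-kB and inflammasome genes 20 were lower, with a median of -0.17 (limma camera, Benjamini-Hochberg adjusted p = 1.19e-04; adjusted p = 0.381 with an estimated correlation), Bcl3 (-0.39) among them.

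Among the genes of energy metabolism, the 23 of glycolysis and glucose uptake were not called (median 0.09, mean -0.0019, limma camera, Benjamini-Hochberg adjusted p = 0.296), and those of oxidative phosphorylation and fatty acid oxidation lay on the higher side. All 37 nuclear genes of oxidative phosphorylation were higher, with a median of 0.19 (limma camera, Benjamini-Hochberg adjusted p = 2.62e-07; adjusted p = 0.531 with an estimated correlation). That median was 0.034 after quantile normalization, where the call ended (limma camera, Benjamini-Hochberg adjusted p = 0.119), 0.024 with FPKM rescaled to an equal sum per library (TPM) and 0.11 without saline 3. Of 33 fatty acid oxidation genes 29 were higher, with a median of 0.28 (limma camera, Benjamini-Hochberg adjusted p = 1.45e-08; adjusted p = 0.525 with an estimated correlation), Lpl (0.40) and Acot1 (0.87) among them. That median was 0.12 with TPM, a scaling under which the median of all genes was -0.15. Of the 15 fasting and glucocorticoid response genes 14 were higher, with a median of 0.28, 0 past the limma test over all genes and 3 that rose adjusted over the list alone (limma camera, Benjamini-Hochberg adjusted p = 1.02e-04; adjusted p = 0.352 with an estimated correlation). Pdk4 stood at 216 ± 55.4 FPKM against 132 ± 40.4 with saline (log2 0.72, SE 0.21, limma with Benjamini-Hochberg adjusted p = 0.436). Grouped by the treatment field, the list had a median of 0.023 and was not called.

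All 30 genes of extracellular matrix and fibrosis were lower with encenicline, with a median of -0.52, 0 past the limma test over all genes (limma camera, Benjamini-Hochberg adjusted p = 5.89e-05; adjusted p = 0.531 with an estimated correlation). The mean matrix score per library overlapped between the groups (difference -0.50, exact two-sided permutation p = 0.135). The median was -0.32 without saline 3, and -0.69 with TPM, where the call ended (limma camera, Benjamini-Hochberg adjusted p = 0.172). Of 10 fibroblast marker genes 8 were lower, with a median of -0.25 (limma camera, Benjamini-Hochberg adjusted p = 0.0181; adjusted p = 0.531 with an estimated correlation), a call that ended without saline 3 (adjusted p = 0.212) and with TPM (0.0952). Of 21 macrophage genes 18 were lower, with a median of -0.19 (limma camera, Benjamini-Hochberg adjusted p = 0.00458, and 0.531 with an estimated correlation). Of 19 cytokine and chemokine genes 11 were lower, with a median of -0.16, and of 14 antigen presentation genes 13, with a median of -0.11 (limma camera, Benjamini-Hochberg adjusted p = 0.0349 and 0.0017, and 0.531 for both with an estimated correlation). Medians of the other called lists lay between -0.43 (mesothelial) and 0.26 (mitochondrially encoded). Among these, the mesothelial call ended in 14 alternatives, calcium handling in 10, mitochondrially encoded in 8 and B cell in 6. None of the 14 tested genes named in advance passed. Ccrl2 stood at 5.75 ± 0.284 FPKM with encenicline and 5.58 ± 1.1 with saline (log2 0.06, 95% confidence interval -0.35 to 0.47, limma with Benjamini-Hochberg adjusted p = 0.933). The log2 fold changes were -0.59 for Nppa, -0.12 for Nppb, -0.39 for Myh7, 0.06 for Myh6, -0.71 for Col1a1 and -0.91 for Postn. Without saline 3 those of Nppa and Postn were -0.17 and -0.49, and without saline 5 that of Myh7 was -0.16. They were 0.45 for Chrm2, -0.02 for Ache, -0.14 for Bche, -0.30 for Cd68, -0.13 for Adgre1, -0.02 for Ccr2 and 0.02 for Il1b. The number of lists called fell from 19 to 11 without saline 3. The 8 higher and 11 lower lists became 3 and 12 with quantile normalization, and 8 and 5 with TPM.

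**Figure D2:**
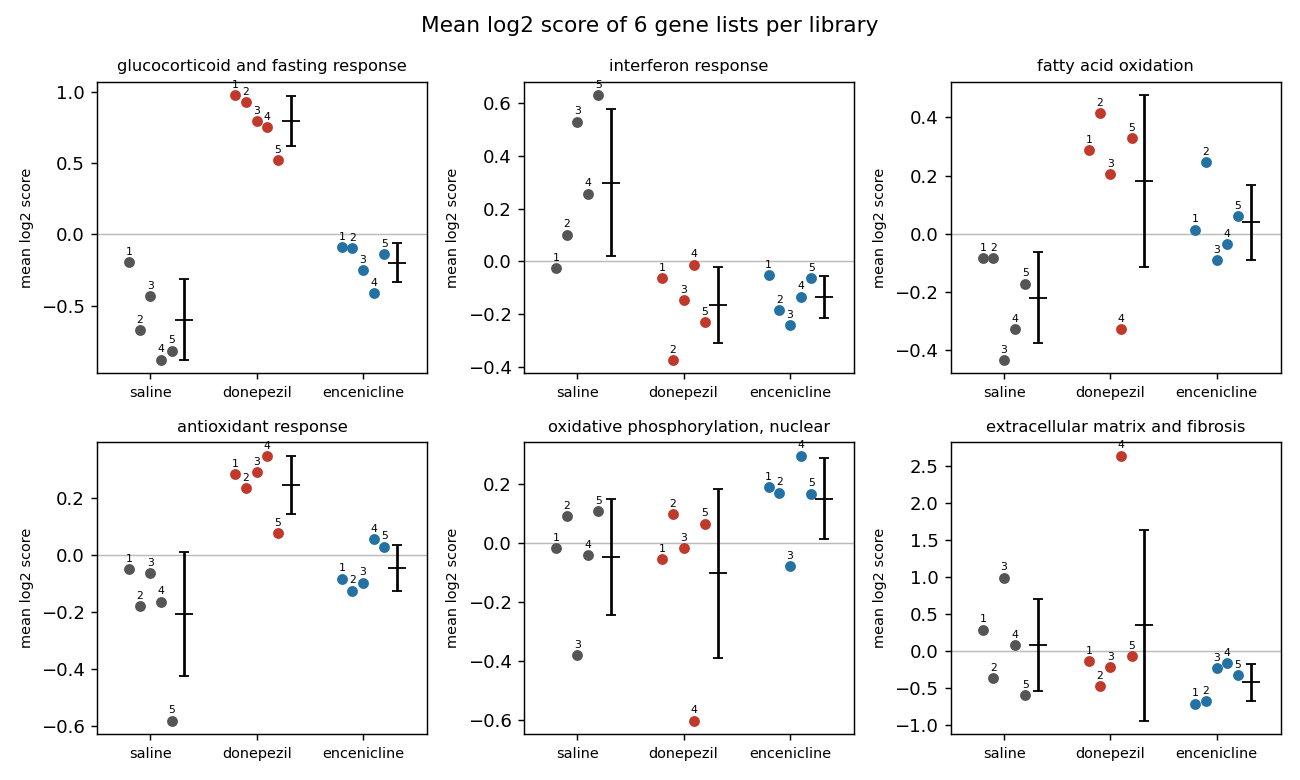
Mean log2 score of 6 gene lists per library, centred on the mean of the 15 libraries, with points labelled by replicate number and a bar at the mean ± SD (n = 5). The fasting and glucocorticoid scores of the donepezil libraries all lie above those of the other 10, and donepezil 4 has a matrix score of 2.64.

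Encenicline against donepezil compared the treatments directly. The fasting genes stood lower with encenicline. Pdk4 was at 216 ± 55.4 FPKM with encenicline and 862 ± 194 with donepezil (log2 -2.01, SE 0.21, limma with Benjamini-Hochberg adjusted p = 0.000193), and Ucp3 at 15.3 ± 2.24 and 52.5 ± 11.1 FPKM (log2 -1.73, SE 0.15, limma with Benjamini-Hochberg adjusted p = 5.80e-05). Of the 15 fasting and glucocorticoid response genes 15 were lower, with a median of -0.65. Pdk4, Ucp3, Angptl4 (-1.89) and Cebpd (-1.13) fell over all genes and 12 fell adjusted over the list alone (limma camera, Benjamini-Hochberg adjusted p = 4.87e-15; adjusted p = 0.00844 with an estimated correlation). The mean score of the list per library separated the 5 encenicline from the 5 donepezil libraries (difference -0.99, exact two-sided permutation p = 0.00794, Benjamini-Hochberg adjusted p = 0.0833 over the lists). Mt2 (-1.86) did not pass (limma with Benjamini-Hochberg adjusted p = 0.14). Of 33 fatty acid oxidation genes 5 fell and 0 rose over all genes, while 18 lay on the higher side with encenicline. The median of that list was 0.08 and it was not called (limma camera, Benjamini-Hochberg adjusted p = 0.419).

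Of the 126 genes called lower with donepezil against saline, 35 were also called higher with encenicline than with donepezil. Gal3st3, a sulfotransferase, was at 6.34 ± 1.29 FPKM with encenicline and 2.1 ± 0.524 with donepezil (log2 1.40, SE 0.17, limma with Benjamini-Hochberg adjusted p = 0.00122). Fam78a was at 4.4 ± 0.413 and 1.44 ± 0.27 FPKM (log2 1.34, SE 0.13, limma with Benjamini-Hochberg adjusted p = 0.000128) and Phyhip at 6.59 ± 0.76 and 3.21 ± 0.309 FPKM (log2 0.93, SE 0.09, limma with Benjamini-Hochberg adjusted p = 0.000193). Lrrc3b (1.33), Rtn4r (1.35), Cited4 (1.22), G0s2 (1.11), Mid1ip1 (1.22), Itgb6 (1.10) and Smim5 (1.02) were among the 35 as well. Rrad (1.37) and Kbtbd13 (0.95) also stood higher with encenicline, without a call between donepezil and saline. Cyp1b1, Rasd1, Hmox1, Chac1, Fam214a, Trp53inp1 and Maff were lower with encenicline, from -1.46 to -1.001. In all 125 genes passed, 59 higher and 66 lower with encenicline, 122 of them protein coding, and 22 differed by at least 2-fold (10 higher, 12 lower). At an unadjusted p under 0.05 there were 2010 genes, 15.0% of those tested.

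Among 18 ion channel and gap junction genes, Gja1, the main gap junction gene of the ventricle, was at 24.7 ± 3.95 FPKM with encenicline and 13.3 ± 1.84 with donepezil (log2 0.86, limma with Benjamini-Hochberg adjusted p = 0.0414), and the pacemaker channel gene Hcn4 passed at 0.71. The Gja1 call ended in 14 of 26 alternatives and the Hcn4 call in 16 of 25. These 2 were also the ones adjusted over the list alone, and the list median was 0.17 (limma camera, Benjamini-Hochberg adjusted p = 8.64e-04; adjusted p = 0.748 with an estimated correlation). The 37 nuclear oxidative phosphorylation genes were all higher, with a median of 0.24 (limma camera, Benjamini-Hochberg adjusted p = 1.74e-08; adjusted p = 0.748 with an estimated correlation), and 0.11 without donepezil 4. The 30 matrix genes were all lower, with a median of -0.80 and 0 past the limma test over all genes (limma camera, Benjamini-Hochberg adjusted p = 3.43e-06; adjusted p = 0.748 with an estimated correlation). Without donepezil 4 that median was -0.095 and the call ended (limma camera, Benjamini-Hochberg adjusted p = 0.0843). The 18 genes of the TCA cycle had a median of 0.18 (limma camera, Benjamini-Hochberg adjusted p = 0.00359; adjusted p = 0.748 with an estimated correlation), which was 0.048 and not called without donepezil 4 (limma camera, Benjamini-Hochberg adjusted p = 0.334). Of 21 immediate early genes, Fosl2 (-0.91) and Myc (-0.76) fell over all genes, and 1 rose and 5 fell adjusted over the list alone, with a median of -0.16 (limma camera, Benjamini-Hochberg adjusted p = 0.00575; adjusted p = 0.748 with an estimated correlation). That call ended without encenicline 1 (adjusted p = 0.104) or encenicline 2 (0.0826) in limma camera with Benjamini-Hochberg adjustment, with medians of -0.051 and -0.12. The other 4 called lists had medians of -0.44 (stress and fetal genes), -0.19 (complement and coagulation), -0.15 (antioxidant response) and -0.11 (NF-kB and inflammasome), each at limma camera, Benjamini-Hochberg adjusted p = 0.0487. Of 28 alternatives, these calls ended in 15, 13, 17 and 19, and without donepezil 4 all 4 ended, with medians of -0.20, -0.12, -0.090 and -0.0135. Of the 10 lists called by camera in this comparison, the fasting list alone was also called with an estimated correlation and by limma fry (Benjamini-Hochberg adjusted p = 5.25e-05). The 10 became 5 without encenicline 2 and 6 without encenicline 1 or without donepezil 4.

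Of the genes named in advance none of the 14 tested passed between the drugs. The log2 fold change of Ccrl2 was -0.26 (95% confidence interval -0.67 to 0.14, limma with Benjamini-Hochberg adjusted p = 0.528), -0.11 without donepezil 2 and -0.45 without donepezil 4. The changes were -1.38 for Nppa, 0.44 for Nppb, -1.08 for Myh7, 0.05 for Myh6, -0.92 for Col1a1 and -1.04 for Postn. Without donepezil 4 they were -0.76 for Nppa, -0.46 for Myh7, -0.18 for Col1a1 and -0.092 for Postn, and without donepezil 2 that of Nppb was -0.20. They were 0.45 for Chrm2, 0.22 for Ache, -0.01 for Bche, -0.06 for Cd68, 0.19 for Adgre1, 0.04 for Ccr2 and 0.18 for Il1b. With 1 library left out, Adgre1 ran from 0.094 (without donepezil 1) to 0.49 (without donepezil 4) and Il1b from 0.034 (without encenicline 3) to 0.35 (without donepezil 4). With donepezil 1 and encenicline 1 left out 27 genes passed, 26 of them among the 125, and grouping by the treatment field gave 0. The count was 51 without donepezil 1, 72 without donepezil 2, 48 without encenicline 2, 67 without encenicline 4 and 57 without encenicline 5.

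The donepezil group stood apart from both others in 79 genes called against saline and against encenicline, 44 of them higher and 35 lower with donepezil than in both other groups. Independent lists of these sizes, matched on direction, would share 1.33 genes. Simulated unchanged groups that share a group in the same way had 0 called genes in common in each of 50 simulations, but these hold no donepezil effect, so neither number gives the overlap that the shared donepezil libraries bring. Across the 13396 genes, which are not independent replicates, the fold changes of the drugs against saline correlated with r = 0.423. Unchanged groups compared with the same saline libraries gave a mean r of 0.439 (-0.00286 to 0.824 over 100 simulations), and r averaged 0.0602 (-0.139 to 0.182) over 20 splits that gave each drug saline libraries of its own. The covariance was 0.0208 against a simulated 0.0146 (-3.58e-05 to 0.0448), a difference of 0.00619.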

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

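The tests of daily clock, libraries with conflicting labels, atrial tissue, advanced remodelling, DNA as the source of the matrix genes and pairs of saline libraries were chosen after the results were seen; the tests of PPAR targets, glucocorticoid receptor targets and receptor genes were written before.

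The first pattern is the rise with donepezil of fasting genes and of some, not most, fatty acid genes. It was called for 13 genes of the 2 lists, among them Pdk4, Ucp3, Angptl4 and Mt2. With a clock index (log2 Dbp minus log2 Npas2) as a covariate their median log2 fold change was 1.32, against 1.29 without it, which argues against the phase of the daily clock as the whole cause, and without donepezil 1 and encenicline 1 it was 1.30, so the rise does not rest on these 2 libraries. Their own scores of the fasting list, 0.98 and -0.088, argue against their treatment fields, since saline libraries reached at most -0.19 and the other donepezil libraries at least 0.52. Targets of PPAR transcription factors and of the glucocorticoid receptor outside the genes already seen were both higher with donepezil (5 against 5 libraries, score difference 0.241, exact two-sided permutation p = 0.0476, Benjamini-Hochberg adjusted p = 0.0635 over 4 lists, which does not pass, and score difference 0.774, exact p = 0.0159, adjusted p = 0.0317). Lower food intake, a higher level of stress hormone or an action of donepezil on the heart may explain the rise, and with no weight, intake or hormone level in the labels these stay open and untested.

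The second pattern is donepezil 4, which accounts for 17 of the 30 values in this part and has 25893 genes above 0 FPKM, against 19789 to 20439 in the other donepezil libraries. Of genes for olfactory and vomeronasal receptors, which the heart hardly transcribes, 15.1% had at least 1 read, against at most 2.27% in any other library, which is consistent with some genomic DNA in the library. Such DNA would not explain its matrix genes, since silent genes reached a mean of 0.0200 FPKM in it, while the median matrix gene was 36.0 FPKM above the other libraries. Of genes abundant in atria, Sln was at 0 and Myl7 at 1.37 FPKM, below the 1.78 of another library, which argues against atrial tissue as the main difference, although Myl4 (0.746; others at most 0.645), Bmp10 (0.0257; others at most 0.0133) and the score of the atrial list (1.77), which includes Nppa, were above every other library. Its deviation from the other donepezil libraries followed, across 13366 genes outside the matrix list (genes are not independent replicates), the slope of each gene on the matrix score within groups in the other hearts (r = 0.366). A library with a matrix score as high as its 2.64 can deviate along such genes whatever raised the score. The correlation therefore cannot tell a heart with more advanced remodelling from another cause, and such remodelling stays a hypothesis.

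In donepezil 4 the mean log2 scores far from the rest of the group were 2.64 for extracellular matrix (others -0.47 to -0.07), 0.85 for fibroblast genes, 0.57 for complement and coagulation and 0.081 for cell cycle on the high side. On the low side they were -0.60 for nuclear oxidative phosphorylation, -0.57 for the TCA cycle, -0.40 for ion channels and gap junctions and -0.33 for fatty acid oxidation. The same library stood apart in the FPKM of Nppa (857.3; others 92.5 to 112), Col1a1 (229; others 13.7 to 20.1), Postn (155; others 3.38 to 6.68) and Lox (39.3). It also did so for Col15a1 (35.2), the macrophage and monocyte genes Adgre1 (8.83) and Ccr2 (2.66), and Lpl, which was low (307; others 460.6 to 491).

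The third pattern is the lower level of interferon response genes in both drug groups than in saline. Over all 10 pairs of saline libraries left out, the median of the 29 genes ran from -0.653 (without saline 1 and saline 2, donepezil) to -0.241 (without saline 3 and saline 5, encenicline), which argues against 1 or 2 saline libraries with high interferon genes as the whole cause. Both drug groups were compared with the same saline libraries, so saline as a group standing high cannot be separated from both drugs lowering these genes, and an unoperated group is not part of the series. Exact two-sided permutation tests of the mean score gave p = 0.00794 for encenicline and p = 0.0159 for donepezil against saline (5 against 5 libraries each), with Benjamini-Hochberg adjusted p = 0.31 and 0.167 over the lists, so neither passes.

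The remaining values each stood far from the other 4 libraries of their group, which chance gives in about 5% of groups; in all, 30 of 390 groups tested had such a library. Encenicline 1, whose label fields differ, was low in Phyhip (5.23 FPKM; others 6.86 to 6.97), Aplnr (9.76) and Myc (1.34) and high in Fkbp5 (14.6) and Map3k6 (10.3; others 5.95 to 6.79). Saline 5 was low in the scores of mitochondrially encoded genes (-0.51) and of antioxidant genes (-0.58) and in Cpt1a (9.25 FPKM). It also had a heat shock score of 1.17 (other saline libraries -0.23 to 0.015) and a clock index of 1.35 (other saline libraries 4.73 to 5.66). Neither of these is among the 30 flagged values. Saline 2 was low in Sgk1 (17.7 FPKM; others 27.7 to 30.2). Donepezil 5 was low in Mt1 (325 FPKM), and donepezil 1, the other library with differing fields, was high in Maff (16.1 FPKM). Encenicline 4 had a high antigen presentation score (0.078) and encenicline 3 a low TCA cycle score (-0.016). No biological explanation was tested for these.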

How the results depend on the processing

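The alternatives without donepezil 4 and saline 5 together and with a clock index as a covariate were added after the data were seen. The 0 genes of encenicline against saline stayed 0 under all 26 alternatives. Of the 52 named genes called between donepezil and saline, 51 stayed called with voom, 43 with scaling without mitochondrially encoded genes and 32 with TPM. Without a filter 26 stayed called, with the 10 libraries alone 22, without donepezil 1 and encenicline 1 22, and with 1 library left out 28 to 52. So 30 of the 52 calls need the encenicline libraries in the fit. Of the 27 called between encenicline and donepezil the numbers kept were, in the same order, 27, 24, 21, 17, 23, 14 and 18 to 27. Calls that ended in 13 or more alternatives were those of Lcn2, Csf1, Gbp3, Gbp7 (13 of 26), Cpt1a (14 of 26), Ucp2, Kdr, Cat, Gbp2 (15 of 26), Psmb8 (16 of 26) and Cxcl9 (16 of 25) against saline, and G0s2, Chac1 (13 of 26), Rrad, Gja1 (14 of 26) and Hcn4 (16 of 25) between the drugs; that of Mt2 against saline ended in 10 of 26. No call reversed, and grouping by the treatment field kept 0 of either. Against saline, Pdk4, Ucp3, Angptl4, Phyhip, Fam78a and Cited4 lost their donepezil call only under that grouping. The fasting and glucocorticoid list kept its call in all 28 alternatives of both donepezil comparisons, with medians of 0.91 to 1.44 (donepezil against saline) and -0.74 to -0.58 (encenicline against donepezil). Drawn splits make chance unlikely for both donepezil counts but cannot exclude it. In 100 splits of the libraries into 5 and 5, 1, the real one, gave as many as 284 genes (highest other 121). Likewise 1 gave as many as 125 (highest other 4). For encenicline against saline the real count is 0, which all 100 of the 100 splits reach by construction (highest other 1), so the splits say nothing about it.

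The 284 genes of donepezil against saline became 82 without donepezil 1 and encenicline 1, 0 by the treatment field, 119 without a filter, 158 with TPM, 63 with the 10 libraries alone, 750 with library weights, 439 without donepezil 4 and saline 5, and 105 (without donepezil 1) to 409 (without donepezil 4) with 1 library left out. The 125 of encenicline against donepezil became 27, 0, 46 and 56 under the first 4 of these, 363 with library weights, 190 with voom, and 48 (without encenicline 2) to 177 (without donepezil 5) with 1 library left out. Fewer libraries may explain part of the falls, although the count against saline rose without donepezil 4. Using no filter brings more genes into the adjustment. The causes of these changes were not tested. The correlation of the drug effects, 0.423, fell to 0.0602 with saline libraries split between the drugs, which removes the shared controls. Replicate numbers do not pair the libraries: 15 pairs with the same number had r of -0.087 to 0.195 (mean 0.0487; 60 other pairs -0.012), 4 of 15 above 0.1, and 4 of 15 libraries were closest to their own number. With the number as a block 0, 298 and 114 genes passed in encenicline against saline, donepezil against saline and encenicline against donepezil.

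Among the single genes named, signs reversed only for genes named in advance that did not pass; the cause was not tested. Of the called lists, the medians of encenicline against saline changed sign with TPM for calcium handling (-0.028), ion channels (-0.027) and antioxidant response (-0.0044), and with the filter at 2 FPKM for cytokines (0.0125). In encenicline against donepezil the immediate early median was 0.049 by the treatment field. In encenicline against saline, log2 fold changes became 0.056 (Ache) and 0.027 (Nppb) without donepezil 1 and encenicline 1, and -0.035 (Ccrl2), 0.0955 (Ache) and 0.024 (Nppb) by the treatment field. They were -0.15 (Myh6), 0.024 (Ccr2) and 0.033 (Ache) with quantiles, -0.032 (Myh6), -0.0265 (Ccrl2) and -0.0325 (Il1b) without mitochondrially encoded genes, and -0.10 (Myh6), -0.095 (Ccrl2) and -0.0635 (Il1b) with TPM. Il1b was -0.0038 with pseudocount 1 and -0.0037 without donepezil 4 and saline 5, and the clock index gave 0.11 (Ccr2) and 0.0035 (Ache). With 1 library left out the ranges were -0.063 to 0.13 (Myh6), -0.038 to 0.1385 (Ccrl2), -0.1464 to 0.2859 (Il1b), -0.16 to 0.080 (Ccr2), -0.094 to 0.056 (Ache), -0.40 to 0.21 (Nppb), -0.26 to 0.018 (Adgre1), -0.24 to -0.053 (Bche) and -0.38 to -0.19 (Cd68).

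In donepezil against saline they became 0.0029 (Chrm2) and 0.0042 (Ccr2) without donepezil 1 and encenicline 1, and 0.13 (Chrm2) and 0.085 (Ccr2) by the treatment field. They were -0.33 (Col1a1), -0.53 (Postn) and 0.022 (Chrm2) with library weights, and -0.16 (Nppa), -0.74 (Col1a1), -1.17 (Postn) and 0.14 (Chrm2) without donepezil 4 and saline 5. Myh6 was -0.026 with quantiles, -0.014 without mitochondrially encoded genes, -0.069 with TPM and -0.028 with the clock index, which gave 0.13 for Ccr2. With 1 library left out the ranges were -0.53 to 0.47 (Col1a1; negative only without donepezil 4), -0.82 to 0.55 (Postn), -0.11 to 0.0785 (Myh6), -0.091 to 0.15 (Chrm2), -0.43 to 0.0899 (Ccr2), -0.33 to 0.11 (Il1b), -0.9981 to 0.0765 (Nppb), -0.23 to -0.047 (Bche), -0.48 to -0.12 (Cd68) and -0.62 to -0.17 (Adgre1).

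In encenicline against donepezil they became -0.0005 (Adgre1) and -0.061 (Ccr2) without donepezil 1 and encenicline 1, and -0.095 (Adgre1) and -0.087 (Ccr2) by the treatment field. Myh6 was -0.13 with quantiles, -0.018 without mitochondrially encoded genes and -0.034 with TPM. Ccr2 was -0.0048 with pseudocount 1, -0.0097 without mitochondrially encoded genes and -0.017 with the clock index. Bche was 0.022 with quantiles, and Cd68 0.0925 with library weights and 0.1805 without donepezil 4 and saline 5. With 1 library left out the ranges were -0.1954 to 0.88 (Nppb), -0.11 to 0.41 (Ccr2), -0.041 to 0.021 (Bche) and -0.18 to 0.1805 (Cd68). At 14496147 to 17176086 reads per library, Chrna7 stayed under the level tested.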

Other observations

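The genes and 2 of the added lists in this part were chosen after the results were seen; the lists of PPAR and glucocorticoid targets were written before theirs. Some genes under glucocorticoid, FoxO and PPAR control outside the fixed lists rose with donepezil. Of 18 glucocorticoid target genes 18 were above 0 and 7 passed, with a median log2 fold change of 0.66, among them Map3k6 (1.32), Errfi1 (1.02), Arrdc3 (0.89) and the glutamine synthetase gene Glul (0.73, limma with Benjamini-Hochberg adjusted p = 0.00901). Of 15 targets of FoxO transcription factors, which act in fasting and muscle breakdown, 13 were above 0 and 2 passed, Gabarapl1 (0.86) and Klf15 (0.86), with a score difference of 0.350 (5 against 5 libraries, exact two-sided permutation p = 0.0159, Benjamini-Hochberg adjusted p = 0.0317 over 4 lists). Of 15 PPAR targets 12 were above 0 and 2 passed, Plin2 (0.66) and Ucp2 (0.73), with a median of 0.18. The 12 genes of fat synthesis and insulin response did not differ in this test (5 against 5 libraries, score difference 0.036, exact two-sided permutation p = 0.373).

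Some genes of resident macrophages, chemokines and vessels fell with donepezil although their lists were not called with all libraries. With encenicline against saline the macrophage and cytokine lists were called lower by limma camera (medians -0.19 and -0.16), but not with an estimated correlation. In that comparison 0 of their members passed over all genes. Timd4, a marker of long-lived resident macrophages, fell from 0.918 ± 0.254 to 0.237 ± 0.127 FPKM (SD, n = 5 each, log2 -0.94, limma with Benjamini-Hochberg adjusted p = 0.00345). Its donepezil values, 0.154 to 0.455 FPKM, all lie below the pseudocount of 0.5, so the size of its log2 fold change depends on that setting. Cbr2, another such marker, fell from 16.9 ± 2.05 to 7.99 ± 0.82 FPKM (log2 -1.04, limma with Benjamini-Hochberg adjusted p = 0.00209). Timd4 and Cbr2 were the 2 of 21 macrophage genes that passed, both over all genes and adjusted over the list alone. The list had a median of -0.19 (limma camera, Benjamini-Hochberg adjusted p = 0.0887, and 0.946 with an estimated correlation). That it was not called depends on single libraries: without donepezil 4, whose score of this list was 0.54 against -0.38 to -0.072 in the other donepezil libraries, the median was -0.39 and the list was called (limma camera, Benjamini-Hochberg adjusted p = 4.00e-05). It was also called without saline 2 (adjusted p = 0.0132) or saline 5 (0.0121) in limma camera with Benjamini-Hochberg adjustment, and the median was -0.085 without saline 3. The growth factor gene Csf1 (-0.60), Cxcl12 (-0.46) and Cxcl9 (-0.77) fell among 19 cytokine and chemokine genes, 3 over all genes and 3 adjusted over the list alone, with a median of -0.20 (limma camera, Benjamini-Hochberg adjusted p = 0.117). That median was -0.062 without saline 3, and the list was called without donepezil 4 (adjusted p = 0.0133), saline 2 (0.0323) or saline 5 (0.0249) in limma camera with Benjamini-Hochberg adjustment. The 6 monocyte genes tested had a median of 0.02 (limma camera, Benjamini-Hochberg adjusted p = 0.835). Of 10 endothelial genes Emcn (-0.61) and Kdr (-0.68) fell over all genes, and 1 rose and 3 fell adjusted over the list alone, with a median of -0.13 (limma camera, Benjamini-Hochberg adjusted p = 0.117) and -0.082 without donepezil 2.

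Pdk4 stood at 1186 FPKM in donepezil 1, labelled saline in its treatment field, against 101 to 197 FPKM in the saline libraries and 668 to 854 in the other donepezil libraries. It stood at 176 FPKM in encenicline 1, labelled donepezil in that field, within the 168 to 299.9 FPKM of the other encenicline libraries. In donepezil 4, silent genes had reads in 15.2% of cases against 1.11 to 2.13% in the other libraries, and silent processed pseudogenes had reads in 791 of 6574 on autosomes and 48 of 804 on the X chromosome.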
